A study of Homo sapiens with 6 samples.

How the data were processed

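RNA of HT-29 xenografts was measured on 6 Affymetrix HG-U133 Plus 2.0 arrays, 2 for each of 3 groups: control tumours, treated tumours, and the untreated tumours on the opposite side of the treated animals. Per the labels the RNA of each group was pooled and the 2 arrays of a group are technical replicates of that pool, with biotin-labelled cRNA made from total RNA of dissected frozen sections. The deposited values are on the log2 scale, and GCRMA is credited to the submitters' processing notes, which give no version. GCRMA corrects the background, applies quantile normalization across arrays and summarises the probes of each probe set. The log2 scale was read from the range of the values. The table held 54675 probe sets, and all 6 columns shared a lowest value of 2.37, at which 27.8% to 28.5% of the probe sets of each array lay. No depth applies to arrays, and their number limits the precision.

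Probe sets were paired with genes through the annotation of the platform and a table of current gene symbols. Of the probe sets, 41097 named 1 gene, 1801 named several and 11777 named none, and 41043 of those with 1 gene were matched by their Entrez identifier. Each of 19775 genes was represented by its probe set with the highest mean over the 6 arrays. Probe sets with several genes or none were left out of the gene comparisons. Genome coordinates were left out because no assembly was named with them.

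With 1 pool per group no test between conditions was made. The 2 arrays of a pool were averaged, and a gene was called higher or lower when the pool means differed by at least 1 on the log2 scale, all 4 array-to-array differences had that sign and both arrays of the higher pool were at or above 5. Where the lower pool lay below 5, folds were computed against 5. The 30 gene lists were fixed before the data were examined, together with the comparisons, the size rule and the rule for naming genes. A list was summarised by the median difference over its genes with a pool at or above 5, where at least 3 had one, and placed among 10000 random lists of the same size, each gene being drawn from the 50 genes nearest to it in mean expression. A list outside the central 95% was counted as shifted, which describes these pools only. The genes named were the 10 largest differences in each direction past the size rule (5 for the opposite side against control), all heat shock and BAG genes past it in treated against control, up to 4 members with the largest absolute difference of each list, and members of lists with a count of 5 or fewer. IFT25 and MYL11 are current symbols of HSPB11 and MYLPF.

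The alternatives were other floors, other minimum differences, no required agreement of array pairs, averaging on the linear scale, setting the arrays to the same median, quantile normalization, other choices of probe set, leaving out each array in turn, and limma over the 6 arrays with and without the technical replicate number as a block. The set test camera was run with a preset correlation of 0.01 and with an estimated correlation. Setting the arrays to the same spike-in median and camera with the estimated correlation were added after seeing the data. The limma and camera fits compare these pools against array error, not the conditions. With 6 arrays in 3 groups, camera with the estimated correlation has few degrees of freedom. A list that it does not call is therefore not shown to be unshifted. Adjusted p values are those of Benjamini and Hochberg.

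The size rule was run on data simulated with array error alone. It called 100 of 100 genes changed by 1.5, 0 of 100 changed by 0.5 and 0 of 19575 unchanged genes. The simulated changes lay on either side of the minimum difference of 1, so these counts followed largely from the settings. No spread between tumours was simulated, so the counts give no error rate for the calls between pools. In the same simulation 8 of 200 random lists of unchanged genes lay outside the central 95%. Errors were drawn independently for each gene, so this share also followed largely from the settings. It gives no error rate for lists of genes that vary together. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.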

Results

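Gene expression was measured in xenografts of HT-29, an established human colorectal adenocarcinoma cell line, which had been injected into both femoral regions of immunodeficient Balb/c (nu/nu) mice. On day 18 after the injection the treated animals received modulated electro-hyperthermia, a heating of the tumour by an electromagnetic field, for 30 min, and tissue was taken 4 h later. The 6 arrays (1-colour, human, 54675 probe sets) covered 3 groups: tumours of control animals, treated tumours, and the untreated tumours on the opposite side of the treated animals. Each group was 1 pool of RNA hybridised to 2 arrays, which the labels call technical replicates. The comparisons therefore describe 3 pools, there was no replicate check between animals, and no test between conditions was possible. The number of arrays limits the precision, and every SD below is that of the 2 technical arrays of a pool.

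The 2 arrays of a pool were nearly the same, and the pools differed from each other by more than the arrays of a pool did. Over the 12992 probe sets with a pool mean at or above 5 (log2), 0 differed 2-fold between arrays of the same pool, and 67 to 145 did so between arrays of different pools. The median absolute difference was 0.050 to 0.059 within a pool and 0.142 to 0.168 between pools. Of the probe sets on each array, 22.3% to 22.8% lay at or above 5. A gene was called higher or lower where the pool means differed by at least 1 (2-fold), all 4 array-to-array differences had that sign, and both arrays of the higher pool were at or above 5. Genes at or above 5 are called detected, and where the lower pool lay below 5 the fold is given against 5, as a lower bound. Log2 differences and rankings are those of the pool means as measured, including means below 5.

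The treated pool was compared with the control pool to see which genes differed 4 h after heating. Of 19775 genes, 45 were higher in the treated pool and 7 were lower, and 7204 genes had a mean at or above 5 in either pool. Genes of the heat shock response made up 10 of the 45. HSPA6, a strictly inducible HSP70 chaperone, was at least 13.1-fold higher, at 8.71 ± 0.023 in the treated pool against 4.85 ± 0.048 in the control pool (SD, 2 arrays each). CRYAB, the small heat shock protein alpha-B crystallin, was at least 4.26-fold higher, at 7.09 ± 0.021 against 4.10 ± 0.183. The other genes among the 10 largest differences of pool means were HBE1, annotated as embryonic haemoglobin epsilon, at 36.4-fold, DNAJB1 at 3.77-fold, HSPH1 at 3.71-fold and BAG3 at 3.62-fold, and 4 genes whose control mean lay below 5. These were the probe set annotated with the mouse symbol Igk (immunoglobulin kappa) at no less than 2.46-fold, the chemokine CXCL8 at 2.44-fold, C5orf46 at 1.94-fold and the skeletal muscle actin ACTA1 at 1.21-fold. In all, 17 of the 45 higher and 3 of the 7 lower genes had a lower pool below 5. The second HBE1 probe set stood at the lowest value of the table, 2.37, in every pool, and the second CXCL8 probe set lay at 2.47 in the treated pool and 2.44 in the control pool.

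**Figure D1:**
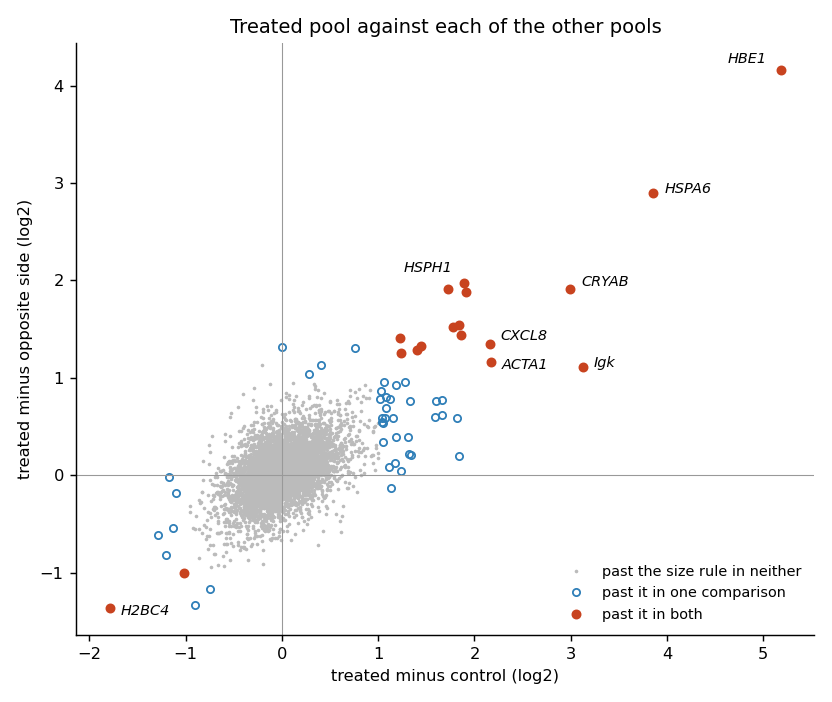
Difference of pool means (log2) between the treated pool and the control pool on the x axis and between the treated pool and the opposite-side pool on the y axis, for the 7267 genes with any pool at or above 5, with 1 point per gene. Filled points mark the 18 genes past the size rule in both comparisons and open circles the 40 past it in 1 of them. HBE1 lies farthest out at 5.18 and 4.16, and HSPA6 follows at 3.86 and 2.89.

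Of the HSP70 family, 8 of 13 measured genes reached 5 in the treated or the control pool, 2 of these 8 were higher and 6 did not pass the size rule. The probe sets shared by HSPA1A and HSPA1B, and those shared by HSPA8 and other genes, are outside these counts and the list median. Their values are given under the other observations. The 2 were HSPA6 and HSPH1, the HSP110 partner of HSP70, which stood at 9.72 ± 0.0092 against 7.83 ± 0.120. HSPA5, the chaperone of the endoplasmic reticulum, differed by 0.57 and HSPA4 by 0.51. The median of the list was 0.38 higher in the treated pool, at the 99.9th percentile of 10000 random lists matched on expression. The set test camera of limma, which compares these pools against array error and not the conditions, gave adjusted p = 0.153 with an estimated correlation. Among 20 detected HSP40 genes, DNAJB1, which activates HSP70, was higher by 1.91 and 19 did not pass. The median of that list was 0.08, at percentile 95.4. In the list of HSP90 and its co-chaperones, HSP90AA1, the inducible HSP90, was higher by 1.09 and the co-chaperone CHORDC1 by 1.22, while 12 of 14 genes did not pass and the ubiquitin ligase STUB1 differed by -0.43. The list median was 0.18, at percentile 99.7 (adjusted p = 0.262 by camera with an estimated correlation).

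Of the 3 detected small heat shock protein genes, CRYAB and HSPB1 (the chaperone HSP27) were higher, the latter by 1.40, and IFT25 differed by 0.29. Their median was 1.40, at percentile 99.98 (adjusted p = 0.153 by camera with an estimated correlation). BAG3, a co-chaperone of HSP70, was the only gene of 5 in the BAG family that passed, at 9.79 ± 0.049 against 7.93 ± 0.028, whereas BAG4 differed by 0.85 and BAG1 by -0.56. The BAG list had a median of -0.02 (percentile 49.0) and a mean of 0.39. Of 12 other genes linked to the heat shock factor HSF1, ZFAND2A was higher by 1.84 and SERPINH1, a collagen chaperone, by 1.28, and the list median was 0.14 (percentile 97.4). No chaperonin of 12 passed the rule, with HSPE1 at 0.46 and HSPD1 at 0.45 and a list median of 0.10 (percentile 90.2).

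**Figure D2:**
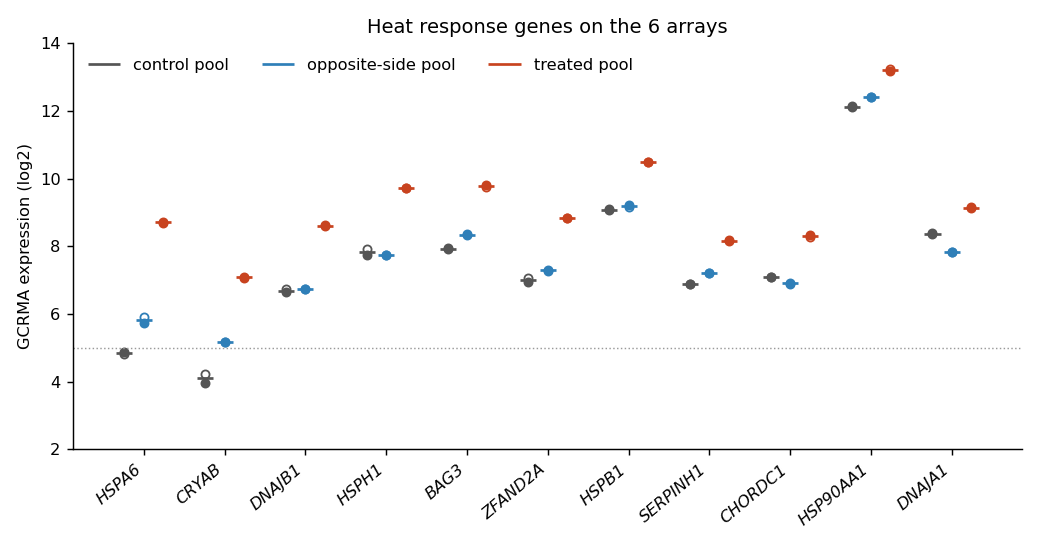
GCRMA expression (log2, y axis) of the 11 heat response genes past the size rule in either comparison of the treated pool (x axis), with 1 circle per array, filled for the first and open for the second array of a pool, and a bar at the pool mean. The dotted line marks 5. The treated arrays lie above the arrays of both other pools for all 11 genes, and CRYAB stands at 4.10 in the control, 5.18 in the opposite-side and 7.09 in the treated pool.

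Of 22 detected immediate early genes 3 passed, namely the transcription factor EGR1 (1.78) and the matrix-associated CCN2 (1.06) and CCN1 (1.04), and all 3 were higher. MYC, at 0.9995, fell just short of the minimum difference of 1. The list median was 0.13, at percentile 99.6 (adjusted p = 0.153 by camera with an estimated correlation). Among 8 genes of the NF-kB and inflammatory list only CXCL8 passed (at least 2.44-fold, control mean 4.13). TNFAIP3 at 0.98, CXCL1 at 0.91 and PTGS2 at 0.82 did not, and the list median of 0.61 lay above all 10000 random lists (adjusted p = 0.153 by the same test). Of 6 metallothionein genes, which encode metal-binding proteins, MT1F was higher by 1.59, MT1X differed by 0.94 and MT2A by 0.71, with a list median of 0.47 (percentile 99.9; adjusted p = 0.153 by the same test). The other MT1F probe set, below 5 in both pools, differed by 0.42 and the other MT1X probe set by 0.43. The list of danger signals had 1 of 8 genes past the rule, HSP90AA1, which the HSP90 list also holds. ANXA1 differed by 0.95 there, and the median was 0.36 (percentile 99.9; adjusted p = 0.153 by the same test).

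The lists of the unfolded protein response and of cholesterol synthesis shifted without any gene past the rule. The 27 unfolded protein response genes had a median of 0.19 (percentile 99.98; adjusted p = 0.153 by camera with an estimated correlation), with HSPA5 at 0.57, XBP1 at 0.40, PDIA6 at 0.38 and ASNS at 0.36. The 13 cholesterol synthesis genes had a median of 0.15 (percentile 98.9; adjusted p = 0.185 by the same test), with SQLE, the squalene epoxidase, at 0.56.

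The medians of the histone, hypoxia and interferon lists lay below 0 in the treated pool, with 1 gene past the rule in the histone list and 0 in the others. H2BC4, a histone H2B gene, was lower, at 3.67 ± 0.087 against 5.46 ± 0.086 (at least 1.38-fold). No other gene of the 9 detected histone genes passed the rule, H1-2 differed by -0.86, and the list median was -0.29 (percentile 0.19; adjusted p = 0.191 by camera with an estimated correlation). The 25 genes of hypoxia and glycolysis had a median of -0.18 (percentile 0.030; adjusted p = 0.153 by the same test), and 20 of the 25 were below control in all array pairs, 3 above. ANKRD37 differed by -0.90, the vasodilator peptide gene ADM by -0.75, EGLN3 by -0.65 and PDK1 by -0.57. The 7 interferon response genes had a median of -0.31 (percentile 0.53; adjusted p = 0.359 by the same test), with GBP2 at -0.53, ISG15 at -0.40, ISG20 at -0.31 and IRF1 at 0.34, and 2 of the 7 were above control in all array pairs. The remaining genes that were lower were SMIM31 (at least 1.69-fold), the ribosomal RNA precursor gene RNA45SN5 (-1.20), NEK5 (at least 1.95-fold), RALGAPA2 (-1.13), FBXO32 (-1.10), which encodes a ubiquitin ligase subunit, and ASH1L-AS1 (-1.02). The other RNA45SN5 probe set differed by -1.52, while the 6 control probe sets for ribosomal RNA on the array differed by -0.65 to 1.81. The other probe sets at or above 5 differed by -0.17 and -0.13 for FBXO32, -0.40 and -0.45 for RALGAPA2 and -0.30 for NEK5.

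Some markers of skeletal muscle and of fibroblasts and matrix differed between the pools as well. Whether their signal came from host tissue or from the tumour cells was not resolved. Among 4 detected skeletal muscle markers, ACTA1 was at least 1.21-fold higher in the treated pool (control mean 3.10) and the fast muscle myosin light chain MYL11 was higher by 1.60, TNNT1 differed by -0.45 and TNNT3 by 0.06, and the list median was 0.83 (percentile 99.9; adjusted p = 0.310 by camera with an estimated correlation). Among 4 detected fibroblast and matrix markers, TAGLN was higher by 1.66 and vimentin (VIM) by 1.14, COL1A1 differed by 0.67 and FN1 by 0.01, and the median of 0.90 lay above all random lists (adjusted p = 0.262 by the same test). The other probe sets of TAGLN, COL1A1 and VIM all lay below 5. Of the endothelial, the leukocyte and the adipose and epidermal markers 1 gene each was detected, FLT1 (-0.04), LYZ (0.23) and KRT10 (-0.08), and of 5 measured red blood cell markers 0 were. The probe set at the 5′ end of ACTB, a measure of RNA integrity and labelling, was 1.12 higher in the treated than in the control pool and that at its 3′ end 0.23 higher, while for GAPDH the differences were -0.46 and -0.03.

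The remaining lists lay inside the central 95% of random lists. Their medians in the treated minus control comparison were 0.06 for 14 p53 target genes, 0.05 for 20 apoptosis regulators, 0.05 for 14 colon epithelium markers, 0.03 for 17 oxidative stress genes, 0.03 for 29 cell cycle genes, 0.01 for 28 proteasome genes (-0.0038 with the spike-in scaling and -0.01 with quantile normalization), -0.07 for 24 ribosomal protein genes and -0.07 for 11 genes of MHC class I and antigen processing. In these 8 lists 1 gene passed the rule, LGR5, a marker of intestinal stem cells, which was at least 1.48-fold higher (control mean 4.13) and whose second probe set lay at 2.52 in the treated pool. The largest difference among the others of each list was -0.81 for AKR1B10, 0.66 for CFLAR, -0.64 for TFF3, 0.58 for PSMD12, 0.52 for TIGAR, 0.49 for CCND1, -0.36 for PSMB8 and -0.24 for RPL19. These are values of the probe set that represents each gene. Another probe set of the colon marker MUC1 differed by -1.03 and another of the apoptosis regulator MCL1 by 1.26 (control mean 4.59). The other CFLAR probe sets at or above 5 differed by 0.60, -0.25 and -0.13. In all, 14 of 26 lists with at least 3 detected genes lay outside the central 95%, where 1.3 would if the genes of a list varied independently. Camera with an estimated correlation, added after seeing the data, called 0 of the 26, with a lowest adjusted p of 0.153. With the preset correlation, camera put most shifted lists below 0.05, from adjusted p = 0.0014 for hypoxia to 0.031 for histones. Among the shifted lists it did not call HSP90 (0.064), muscle (0.148) or interferon. It also called lists inside the central range, namely HSF1-linked genes (0.0097), ribosomal proteins (0.024), chaperonins (0.031) and HSP40 (0.033).

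**Figure D3:**
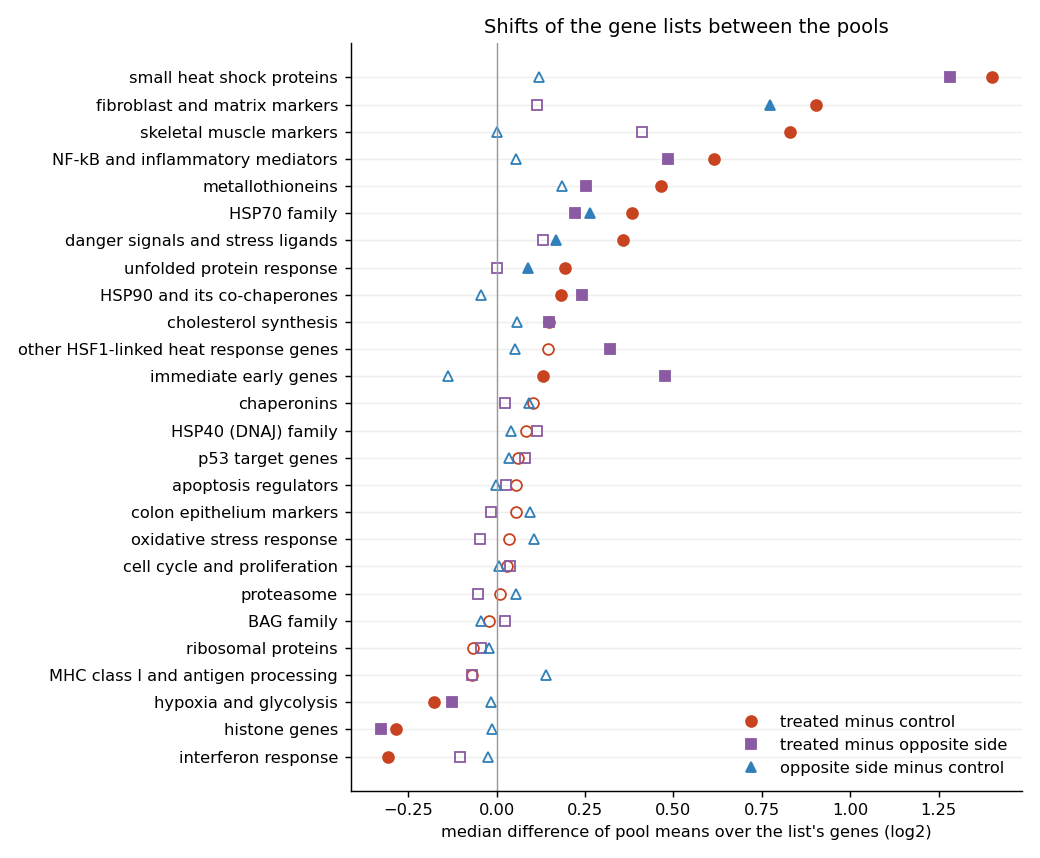
Median difference of pool means (log2, x axis) over the detected genes of each of the 26 lists (y axis) for the 3 comparisons, with filled symbols where the median lies outside the central 95% of 10000 random lists matched on expression. Small heat shock proteins lie farthest to the right, at 1.40 against control and 1.28 against the opposite side, and the histone and hypoxia lists lie left of 0 in both comparisons of the treated pool.

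The treated pool was next compared with the tumours on the opposite side of the treated animals to see which genes differed between heated and untreated tumours of the same animals. Here 20 genes were higher and 4 lower in the treated pool, among 7155 genes at or above 5 in either. HBE1 was 17.9-fold higher and HSPA6 7.44-fold, at 8.71 ± 0.023 against 5.82 ± 0.137. HSPH1 was 3.92-fold, PHLDB2 at least 2.23-fold, CRYAB 3.75-fold, DNAJB1 3.68-fold, ZFAND2A 2.92-fold, EGR1 2.88-fold, BAG3 2.71-fold and CHORDC1 2.65-fold higher. The 4 other PHLDB2 probe sets lay below 3 in the treated pool. The lower genes were ASH1L-AS1 (-1.01) and the gene annotated as MIRLET7D (-1.17). Whether the MIRLET7D probe set reports the microRNA itself was not examined. With treated means below 5, SIN3A (4.97 against 6.31) and H2BC4 (3.67 against 5.04, which is 1.03-fold when taken against 5) were lower too. Without the probe sets of the _x_at and _s_at kinds the difference of SIN3A was 0.001, on a probe set at 4.29 in both pools, below the level at which genes were called. In the lower pool 7 of the 20 higher and 2 of the 4 lower genes lay below 5. The GAPDH probe sets differed by -0.45 at the 5′ end and -0.03 at the 3′ end, and those of ACTB by -0.16 and 0.08.

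Across the 7 heat response lists 9 of 74 detected genes were higher than in the opposite-side pool, 8 of them also higher than in the control pool, and 0 were lower in any comparison. Of the HSP40 list DNAJA1 was higher by 1.30 in addition to DNAJB1, and HSPB1 was higher by 1.28. Of all 26 lists 10 lay outside the central 95%, and for each of these 10 camera with an estimated correlation gave adjusted p = 0.275. With the preset correlation adjusted p by camera ran from 1.3e-04 for immediate early genes to 0.098 for cholesterol synthesis. The median was 0.22 for the HSP70 list (percentile 99.4), 0.24 for the HSP90 list (above all random lists), 1.28 for small heat shock proteins (percentile 99.99) and 0.32 for the other HSF1-linked genes (above all random lists). Immediate early genes had a median of 0.48 (above all random lists) with EGR1 past the rule. The NF-kB list had 0.48 (percentile 99.9) with CXCL8 past the rule (at least 2.44-fold), the metallothioneins 0.25 (percentile 98.5) and cholesterol synthesis 0.15 (percentile 98.5), the last 2 with no gene past the rule. Lower were the histone list at -0.33 (percentile 0.050) and the hypoxia list at -0.13 (percentile 0.21).

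The muscle list (0.41, percentile 96.2) and the matrix list (0.11, percentile 78.3) stayed inside the central range in this comparison, with ACTA1 past the rule (at least 1.21-fold). So did HSP40 (0.11), the chaperonins (0.02), BAG (0.02), danger signals (0.13), p53 targets (0.08), cell cycle (0.04), apoptosis regulators (0.03), the unfolded protein response (0.0005), colon markers (-0.02) with LGR5 past the rule (at least 1.48-fold), ribosomal proteins (-0.05), oxidative stress (-0.05), the proteasome (-0.05), MHC class I (-0.07) and interferon response (-0.10). The 40 detected spike-in control probe sets, added in fixed amounts, were higher on the treated than on the opposite-side arrays by a median of 0.33, against 0.105 for treated minus control. Setting all arrays to the same spike-in median, an alternative chosen after seeing the data, shifted every treated minus opposite difference by -0.19, less than the median spike-in difference itself. The counts then were 16 higher and 15 lower, and the medians of the HSP40, BAG, cholesterol, danger signal, p53, chaperonin, apoptosis, cell cycle, unfolded protein response and matrix lists turned negative, while the other lists with a positive median were left at 0.03 for HSP70, 0.05 for HSP90, 0.06 for metallothioneins, 0.12 for NF-kB, 0.13 for HSF1-linked, 0.22 for muscle, 0.29 for immediate early and 1.09 for small heat shock protein genes.

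The opposite-side pool was compared with the control pool to see which genes differed in the untreated tumours of the treated animals. Of the genes, 17 were higher and 12 lower in the opposite-side pool, with 7182 at or above 5 in either. Of the 5 genes with the largest differences of pool means, 2 had a control mean above 5, namely VIM (2.40-fold, at 7.78 ± 0.0099 against 6.51 ± 0.292) and the cysteine protease cathepsin Z (CTSZ, 2.30-fold). The others, with control means below 5, were Igk (at least 1.14-fold), C5orf46 (at least 1.69-fold) and the matrix glycoprotein thrombospondin (THBS1, at least 1.76-fold). On the lower side they were CEMIP (-1.32), which encodes a hyaluronan-binding protein, PRR5L (-1.18), TMEM44 (-1.17) and, with opposite-side means below 5, SND1-IT1 (at least 1.24-fold) and the adrenergic receptor gene ADRA2A (at least 1.36-fold). The other probe sets of VIM, THBS1, CTSZ and CEMIP lay below 3 in the opposite-side pool, and that of PRR5L at or above 5 differed by -0.65. In the lower pool 7 of the 17 higher and 5 of the 12 lower genes lay below 5. With the spike-in probe sets at the same median the counts were 32 higher and 4 lower, every difference having shifted by 0.18.

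The matrix list stood apart in this comparison too, with a median of 0.77 (above all random lists; adjusted p = 0.467 by camera with an estimated correlation) and VIM and TAGLN (1.04) past the rule among 4 genes. Another 3 lists lay above the central range, the HSP70 family at 0.26 (percentile 99.4), danger signals at 0.17 (percentile 98.9) and the unfolded protein response at 0.09 (percentile 98.8), with no gene past the rule in any of them. The same test gave adjusted p = 0.467 for the HSP70 list and adjusted p = 0.455 for the others. Camera with the preset correlation gave adjusted p = 0.056 for the matrix and 0.065 for the HSP70 list. For danger signals it gave 0.020 and for the unfolded protein response 0.013. It also gave 0.020 for the metallothioneins, whose median lay inside the central range. HSPA6 differed by 0.97, and among all 7 heat response lists CRYAB alone passed the rule, at 5.18 against 4.10 (at least 1.13-fold). The small heat shock protein list had a median of 0.12 (percentile 82.7). The medians of the remaining lists lay between -0.14 for immediate early genes (percentile 2.60) and 0.18 for metallothioneins (percentile 93.8), and with the spike-in scaling the medians of the immediate early (0.07), HSP90, BAG, apoptosis, interferon, hypoxia, histone and ribosomal lists turned from negative to positive. The ACTB probe set at the 5′ end was 1.28 higher in the opposite-side pool and that at the 3′ end 0.15 higher, while those of GAPDH differed by -0.01 and 0.0005.

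Genes higher in the treated pool against control overlapped with both other comparisons. Of the 45 genes, 16 were also among the 20 higher against the opposite side, and 12 were among the 17 higher in the opposite-side pool against control. On the lower side 2 genes, H2BC4 and ASH1L-AS1, were shared with the first and 1, NEK5, with the second comparison. Each overlap uses 1 pool in both of its comparisons, so the lists are not independent of each other.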

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

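The tests in this part were chosen only after the result was seen, apart from that on the other probe sets of the heat response genes. Each of the next values is a signal in a probe set that the gene comparisons left out because its annotation names no gene or several. A probe set with no gene, at 9.88 in the treated pool, was 6.84 higher there than in the control pool and 2.28 higher in the opposite-side than in the control pool, where it lay at 3.04, below 5. Another with no gene, at 11.97 in the treated pool, was 4.94 higher there than in the control pool and 4.68 higher than in the opposite-side pool. The probe set shared by HSPA1L, HSPA1B and HSPA1A was 2.06 higher in the treated than in the control pool. That shared by UBD and GABBR1 differed by 2.55 in that comparison. A probe set shared by HBA2 and HBA1 differed by 2.40, and the control means of these last probe sets also lay below 5, at 4.35 and 2.65.

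The 10 heat response genes higher in the treated than in the control pool had differences of at least 1.09. Among the 40 spike-in probe sets at or above 5 the largest absolute difference between these pools was 0.249, and below 5 it was 0.43. The genes had been chosen for a difference of at least 1, so their distance from the spike-ins follows in part from the rule. The values were also already normalized, and control probe sets for ribosomal RNA differed by -0.65 to 1.81. Labelling or hybridisation efficiency therefore stays open, though no spike-in differed by as much as these genes. Spike-ins do not report the integrity of the tumour RNA. The probe set at the 5′ end of ACTB differed by 1.12 and that of GAPDH by -0.46, so a part of RNA integrity stays open. The 6 other probe sets at or above 5, of 4 of these genes, were all higher, by 1.04 to 3.82 with a median of 1.23. They differed by 1.22, 1.11 and 1.04 for HSP90AA1, 3.82 for HSPA6, 2.02 for HSPH1 and 1.24 for DNAJB1. For these 4 genes this argues against a fault of a single probe set. RNA of related genes that binds all probe sets of a gene would not be seen in this way. The 2 below 5 differed by 2.02 (HSPH1) and 0.00 (CHORDC1). For the 6 genes with no other probe set at or above 5, probe sets that do not measure their gene stay open. Differences between the tumours unrelated to the treatment stay open: the same 10 genes had a median of 0.287 for opposite side minus control, but 1 pool per group gives no spread between tumours. An effect of the heat treatment may account for the pattern and stays open with it, as untested.

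Some muscle and matrix marker genes lay higher in the treated and in the opposite-side pool than in the control pool, though only VIM and TAGLN passed the size rule in both. Of 8 detected markers 5 were above control in both pools in all array pairs, 1 was below in both (TNNT1) and 2 were neither, so more host tissue in those sections may or may not be a source. The 7 other probe sets of 3 of the 5 genes all lay below 5, the highest at 4.999, and 2 genes had none, so probe sets that do not measure their gene stay open too. These explanations cannot be told apart here, because the probes were designed for human RNA, few markers were detected and each group was 1 pool. A response in the treated animals stays open as untested.

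The probe set annotated to HBE1 was 5.18 higher in the treated than in the control pool. Haemoglobin RNA of blood in the treated sections may be a source: the treated mean was above both other pools for 7 of 10 adult globin probe sets and above them in all array pairs for 3, but only 1 of the 17 other globin probe sets reached 5, and values near the lowest level decide little. Transcription of HBE1 itself stays open as well, since the other HBE1 probe set lay at 2.374, the lowest value of the table, which excludes nothing. The sequence that the probe set detects was not examined.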

How the results depend on the processing

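The alternatives that set spike-in controls to the same median and that estimate the correlation in camera were chosen only after the result was seen. Counts are given as higher, lower for treated against control, treated against opposite side and opposite side against control, where the values above were 45, 7, 20, 4, 17 and 12. A floor of 7 gave 25, 1, 11, 0, 9 and 1. A minimum of 1.5-fold gave 201, 116, 140, 75, 105 and 169, and a minimum of 4-fold 6, 0, 2, 0, 1 and 0, in each case because the rule is wider or stricter. Limma over arrays with no minimum difference gave 1554, 1727, 1601, 1271, 1432 and 1841 genes, and with the size rule the main counts, with or without the replicate block. The mean over a gene's probe sets gave 26 and 4 for treated against control and 5 and 3 for opposite side against control. Without _x_at and _s_at probe sets 10 genes were higher against the opposite side and 11 in the opposite side against control, with fewer genes measured. Spike-in scaling gave 15 lower against the opposite side, and 32 higher and 4 lower for the opposite side against control, having shifted every difference. Leaving out each array gave 45 to 48, 6 to 9, 20 to 22, 3 to 6, 15 to 19 and 12 to 15. Camera with an estimated correlation called 0, 0 and 0 lists, against 15, 7 and 3 with the preset correlation and 14, 10 and 4 by random lists. The cholesterol list against the opposite side turned to -0.0418 with spike-in scaling, and SIN3A to 0.001 without _x_at and _s_at probe sets, on a probe set below 5. Where no reason is given, the cause was not tested. Of all other values for genes, 3361 stayed within the spread between arrays and 604 moved beyond it without a change of sign in called genes, and of those for lists 673 stayed and 310 moved. Genes below 5, most of the table, could not be called.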

Other observations

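The probe sets named here were chosen after their values were seen, and no tests were run on them. Probe sets shared by several HSP70 genes, which the gene comparisons left out, were also higher in the treated pool. The 3 probe sets shared by HSPA1A and HSPA1B, the major stress-inducible HSP70 genes, were higher than in the control pool by 1.80, 2.06 and 1.41 and than in the opposite-side pool by 1.82, 2.07 and 1.66. Between the opposite-side and control pools they differed by -0.03, -0.003 and -0.26. The 4 probe sets shared by HSPA8 and small nucleolar RNA genes within it were 1.27 to 1.57 higher than in the opposite-side pool, and 2 of the 4 passed the size rule against control, at 1.63 and 1.01. A probe set shared by the histone genes H2AC19 and H2AC18 was lower in the treated pool, with differences of -1.07 from control and -1.57 from the opposite side, and their other detected probe set differed by -0.74 and -0.92.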
